A study of Sus scrofa with 2 samples.

How the data were processed

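The data were 2 lists of CUT&Tag peaks for ZBTB16 from wild-type immature spermatogonia of pig testis, 1 list per library, with 100000 cells per library per the labels' protocols. The labels put both libraries in 1 group and number them replicate 1 and replicate 2. The genome build was Sscrofa11.1 per the submitters' processing notes. The aligner, the peak caller, its control and the annotation tool are not given in the sources used here. Peaks were deposited per library, not on pooled libraries, so the lists can be compared by overlap. An IgG negative control described in the labels' protocols was not analysed here, so signal that an unspecific antibody would give was not subtracted by the steps below.

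Per the file headers, each deposited peak carries its position, width, summit, a fold enrichment (a linear ratio over the caller's background), −log10 p-value and −log10 q-value, a score, and the gene, transcript, annotation class and distance to the TSS that the authors assigned to it. The deposited score is 10 times the −log10 q-value as whole numbers and was not used further. The lowest deposited −log10 q-value was 1.31 in both lists, so the authors' threshold lay near q of 0.05. The authors' promoter class held peaks at −2995 to 0 bp from the TSS, and peaks that began just downstream were listed as 5′ UTR, exon or intron. Each peak was assigned to 1 gene, so of a pair of genes sharing a promoter only 1 is counted. The files name chromosomes by number up to 20, and the genes on 19 and 20 were those of X and Y in the gene table for all 10212 and 7246 peaks whose symbol matched (99.4% and 99.2% of the peaks of replicate 1 and replicate 2). In replicate 1, 155 peaks and in replicate 2, 112 peaks lay on unplaced scaffolds and were kept. The numbers given to the peaks skip 16 values in replicate 1 and 11 in replicate 2.

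The sequencing depth of the libraries is not given in the sources used here. The deposited fold and −log10 p-value of each peak fitted a whole number of fragments at the summit and a background by fold = (fragments + 1)/(background + 1) and a Poisson upper tail, within a relative tolerance of 1e-05, for 100% of the peaks of both lists. This gave the summit fragments and the background per peak. The lowest background, which was shared by 347 peaks in replicate 1 and 413 in replicate 2, was 1.21 and 0.979 fragments, a ratio of 1.23, and stands in for relative depth. On 474 simulated peaks 100% of the counts were recovered, and 0.350% of simulated peaks with counts that were not whole passed the same tolerance. Intervals on fragments are exact Poisson and intervals on shares Wilson at 95%, except the exact binomial interval for the X chromosome. They cover counting error only.

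Shared peaks were replicate 1 peaks that overlapped a replicate 2 peak by at least 1 bp, and bedtools 2.31.1 gave the same 5468. Overlap was set against 1000 random placements of the replicate 1 peaks on their own chromosomes. Classes were compared between shared and library-only peaks by two-sided Fisher's exact tests. Genes were the 16509 protein-coding genes of the RefSeq table for Sscrofa11.1 with a unique symbol other than a LOC number. A gene counted as bound when the authors assigned it a promoter peak in both libraries. The 26 gene lists were tested by two-sided Fisher's exact tests against all other genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. They covered germ cell stages, other testis cell types, signalling pathways, HOX genes, chromatin regulators, pluripotency, cell cycle, ribosomal proteins, 4 sets of markers from outside the testis, and genes named in mouse work on ZBTB16, written from general knowledge. On simulated genes, 80.5% of lists of 38 genes with 46 percent bound were called, 100% of such lists with none bound, and 0.850% of unchanged lists of the real sizes. These rates do not hold for smaller lists. In the data, 0 of 15 bound genes gave an unadjusted Fisher's exact p = 0.0524. By promoter peaks in both libraries, a list of 15 genes or fewer therefore could not pass as lower. Chromosome lengths were taken to the last annotated gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

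The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Named are ZBTB16, the 20 genes with a symbol whose promoter peaks had the highest fold in both libraries (by the lower of the within-library percentile ranks), up to 4 bound members and up to 3 members with no peak from each list, all members of the mouse list, and the 5 strongest shared distal peaks. Some genes that this rule would name are not reported here. TBC1D25 and the genes of the prefix families in the closing section were named after their values were seen. The alternatives were a stricter fold, equal list lengths, reciprocal overlap, local random shifts, distal peaks only, a narrower promoter, any assigned peak, another background, other score columns and leaving out each library. Other alternatives were added later and are named as such in the closing section, and the tests of the split of fragments between the libraries and of the distance to gene ends were also chosen after the data were seen. Motif searches and a match on GC content need a genome sequence, which was not used here.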

Results

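Binding of ZBTB16 (PLZF), a zinc finger transcription factor of undifferentiated spermatogonia, was profiled by CUT&Tag in wild-type immature spermatogonia from pig testis. CUT&Tag uses an antibody to bring a transposase to the sites of a chromatin protein and sequences the fragments it releases. The data comprised 1 group of 2 libraries, replicate 1 and replicate 2, each from 100000 cells. The study asked which genes ZBTB16 binds in these cells and which pathways those genes belong to. There was 1 condition, so the comparisons were between the 2 peak lists, between classes of genomic feature and between groups of genes. An IgG control library and knockdown RNA-seq were not analysed here. Replicate 1 held 10273 peaks of median width 506 bp that covered 5716 kb, and replicate 2 held 7301 peaks of median width 470 bp that covered 3795 kb. The median fold enrichment was 4.98 in replicate 1 and 5.0 in replicate 2. The median peak rested on 16 fragments at its summit in replicate 1 and on 14 in replicate 2, so a single peak of median height carried wide counting error. All positions are on Sscrofa11.1, and each fold enrichment is the authors' value for that peak over the background of its own library.

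Peaks at the promoters of DEAF1, a transcription factor, UBXN6, an adaptor of the VCP ATPase, and ZFPM1, a cofactor of GATA factors, were among the strongest in both libraries. In all, 5468 of the 10273 replicate 1 peaks (53.2%, 95% Wilson interval 52.3 to 54.2) overlapped a replicate 2 peak by at least 1 bp. Of the 7301 replicate 2 peaks, 5474 (75%, 74.0 to 76.0) overlapped a replicate 1 peak. Promoter peaks recurred more often than distal intergenic ones: 63.0% of the 6251 promoter peaks of replicate 1 overlapped a promoter peak of replicate 2, against 25.2% of the 1228 distal peaks for distal peaks of replicate 2. Promoter peaks also rested on more summit fragments, at a median of 19 against 11 for distal peaks in replicate 1. Sharing rose with summit fragments, so this contrast is not between peaks of like height. When the replicate 1 peaks on chromosomes were placed at random on their own chromosomes, 0.378% of them overlapped on average and at most 0.652% in 1000 placements (one-sided permutation p = 0.000999, the smallest these placements can give). The placements spread peaks over whole chromosomes, while promoters held most peaks of both lists. Any lists rich in promoters would tend to pass, so the p-value does not separate ZBTB16 binding from unspecific signal.

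Sharing followed the number of fragments at the summit. In replicate 1 it was 15.7% in the lowest quartile by summit fragments (7 to 12 fragments), 40.1% and 66.2% in the middle quartiles, and 90.9% in the highest. In replicate 2 it went from 38.1% in the lowest to 98.4% in the highest quartile. The 5468 shared peaks had a median of 21 summit fragments in replicate 1 and the 4805 replicate 1-only peaks a median of 12. The split of summit fragments between the libraries had a chi-square per degree of freedom of 0.604 over all shared peaks, but a peak has to pass in both lists to be counted here, which narrows that spread. The ratio was higher where this matters less: 0.820 in the 734 shared peaks with at least 60 fragments in both libraries together, and 1.504 in the 64 with at least 120 (chi-square p = 0.00595). Of 1109 replicate 1 peaks with at least 31 fragments, 39 had no replicate 2 peak. If replicate 2 sampled exactly the rate seen in replicate 1, 4.13 would be missed. If the true rate of every one of these peaks lay 2 SD lower, an extreme case, 73.7 would be missed. Among the 732 with a background at or below its 95th percentile, 16 were missed, against 0.336 and 31.9. These values do not settle whether the libraries differ beyond sampling noise, and the labels do not say whether they came from separate animals or cultures. No mean or SD over them is given, and the p-values compare peaks or genes within these libraries only.

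**Figure D1:**
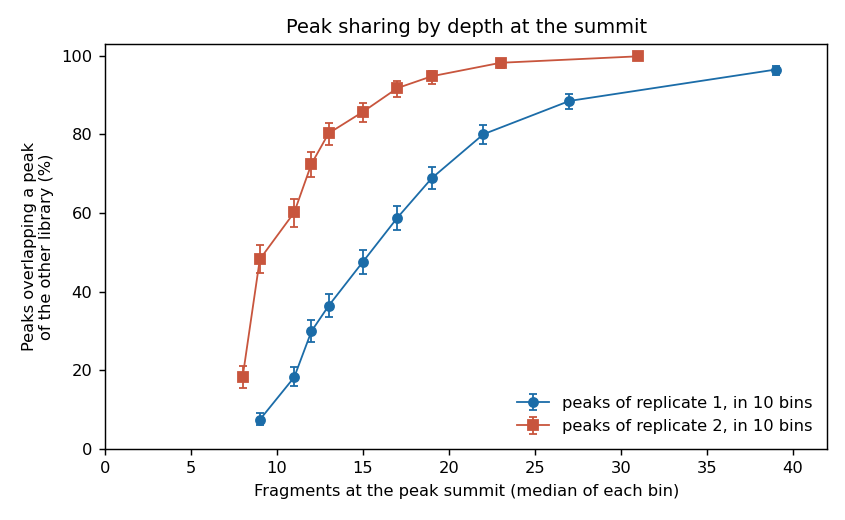
Share of peaks (%, y axis) that overlap a peak of the other library, against the median number of fragments at the summit (x axis) in 10 equal bins of the replicate 1 peaks (circles) and of the replicate 2 peaks (squares); bars are 95% Wilson intervals for counting error. The share goes from 7.40% in the lowest to 96.5% in the highest bin of replicate 1, and from 18.2% to 99.9% in replicate 2.

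Shared peaks lay mainly at promoters, as at CCND3, a D-type cyclin, GSK3B, a kinase of WNT and insulin signalling, and ETV5, an ETS factor needed for spermatogonial stem cell self-renewal. The promoter class of the authors' annotation, which here reached from the transcription start site (TSS) to 3 kb upstream, held 76.4% of the 5468 shared peaks and 43.1% of the 4805 replicate 1-only peaks (odds ratio 4.28, adjusted exact p = 1.83e-264, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 7 classes). The gap was narrower among peaks of like height. By quartile of summit fragments in replicate 1, it went from 49.6% against 26.5% in the lowest to 84.5% against 73.0% in the highest. Distal intergenic peaks made up 5.69% of shared and 19.1% of replicate 1-only peaks (adjusted exact p = 5.70e-99), and intronic peaks 4.72% against 18.4% (adjusted exact p = 5.01e-110). Exonic and 3′ UTR peaks were also less frequent among shared peaks, at 4.22% against 8.78% and 0.750% against 1.56%. The 5′ UTR share (7.52% against 8.16%, adjusted exact p = 0.239) and the share downstream of genes within 3 kb (0.677% against 0.937%, adjusted exact p = 0.174) did not differ past the threshold. By the classes of the replicate 2 peaks, shared against replicate 2-only, the downstream share passed as lower (0.621% against 1.15%, adjusted exact p = 0.0333). The 5′ UTR share was then the higher one among shared peaks (9.04% against 7.72%, adjusted exact p = 0.0846). In the lists as a whole, promoters held 60.8% of replicate 1 and 64.0% of replicate 2 peaks. Neighbouring peaks are not independent, so these p-values understate the counting error.

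**Figure D2:**
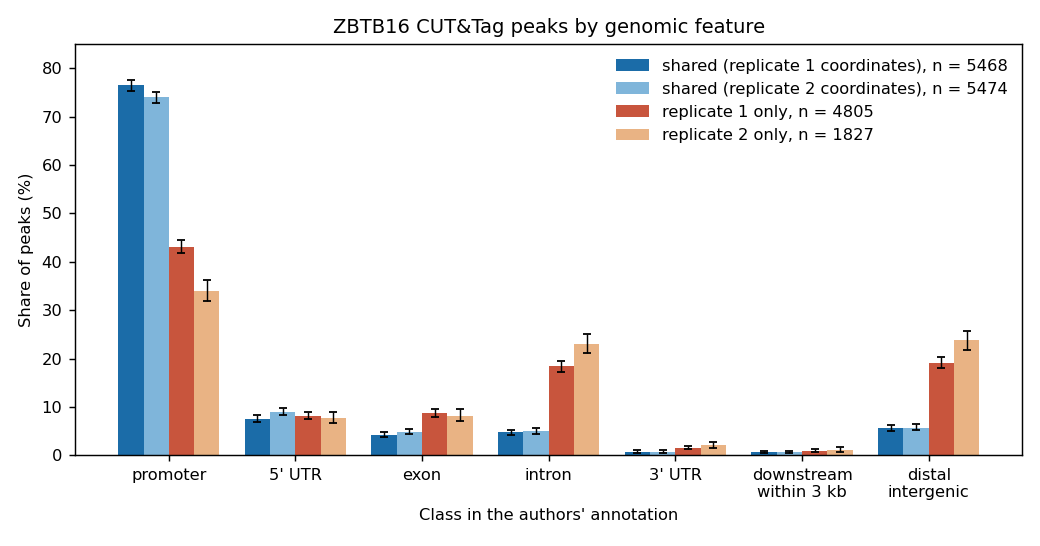
Share of peaks (%, y axis) in each class of the authors' annotation (x axis) for shared peaks with the class of their replicate 1 or replicate 2 peak and for peaks of 1 library only; error bars are 95% Wilson intervals for counting error. Promoters hold 76.4% of shared peaks by their replicate 1 class and 43.1% and 34.0% of the replicate 1-only and replicate 2-only peaks.

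Where a promoter peak overlapped the TSS itself, its summit lay at a median of 3 bp upstream in both libraries, and 70.4% of the 5169 such summits in replicate 1 and 71.9% of the 3851 in replicate 2 were within 200 bp of the TSS. Only peaks spanning the TSS entered here. Promoter peaks had median widths of 593 and 527 bp, so this choice by itself keeps summits near the TSS on both sides. No random expectation was computed, so these values do not show that binding centred on the TSS. At ETV5 the summit was 9 bp upstream of the TSS in replicate 1 and 12 bp upstream in replicate 2. Of the 5385 shared peaks on chromosomes, 78.3% lay within 1 kb of either end of a protein-coding or lncRNA gene, against 5.45% of randomly placed peaks (permutation p = 0.000999, the smallest 1000 placements can give). The random placement made no allowance for signal that an unspecific antibody would give near gene ends.

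At the gene level, 3439 of 16509 protein-coding genes with a symbol (20.8%) had a promoter peak in both libraries, with 5415 in replicate 1 and 4115 in replicate 2. Independent lists of these lengths would share 1350 genes (odds ratio 26.8, with a two-sided Fisher's exact p too small to be represented). DEAF1 had the strongest promoter peak of a gene with a symbol (chromosome 2, 427633 to 428215, its nearest edge 49 bp upstream of the TSS), with a fold enrichment of 17.4 in replicate 1 and 18.4 in replicate 2. Its summit held 204 fragments in replicate 1 (exact 95% Poisson interval 177 to 234) and 179 in replicate 2 (154 to 207). UBXN6 followed on chromosome 2 (74357126 to 74357697) at 12.6-fold and 12.3-fold, then ZFPM1 on chromosome 6 (1153832 to 1154320) at 12.2-fold and 11.5-fold. CDCA2, a regulator of protein phosphatase 1 on mitotic chromatin, had 11.7-fold and 11.2-fold (chromosome 14, 9517636 to 9518466). Genes of chromatin and transcription among the 20 strongest were KDM4A, a histone H3 lysine demethylase (11.3-fold and 10.2-fold), TDG, the thymine DNA glycosylase of active DNA demethylation (11.2-fold and 9.88-fold), CNOT9, a subunit of the CCR4-NOT deadenylase (11.9-fold and 9.91-fold), ATF7 (10.96-fold and 10.1-fold), CIC, a transcriptional repressor (10.1-fold and 9.84-fold), and ZNF146 (10.4-fold and 9.47-fold). Genes of genome maintenance were MMS19, a factor of iron-sulphur protein assembly (11.09-fold and 10.3-fold), and SWSAP1, which acts in homologous recombination (9.92-fold and 9.85-fold). The mitochondrial genes were NDUFA11 (10.5-fold and 10.5-fold), COQ7 (10.6-fold and 9.86-fold), TOMM40 (10.3-fold and 9.68-fold) and ALDH6A1 (10.1-fold and 10.0-fold). The list was completed by AP2A1 (12.1-fold and 10.95-fold), EVI5L (10.9-fold and 10.3-fold), RPP40 (10.9-fold and 11.9-fold) and DMXL1 (9.87-fold and 10.6-fold). Of these 20 genes, CIC had its peak farthest from the TSS, with its nearest edge 1344 bp upstream in replicate 1. The recovered background in replicate 1 had a 95th percentile of 5.66 fragments over all shared peaks. It lay below that at MMS19, KDM4A, RPP40, ATF7, TDG, COQ7, SWSAP1, ZNF146 and DMXL1. At the rest of the 20 genes it lay above, such as DEAF1 (10.8), UBXN6 (8.75) and CIC (11.3).

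ZBTB16 itself (chromosome 9, 41639536 to 41839254) had no peak within the gene in either library. The nearest peak within 50 kb was in replicate 1 only, 21.5 kb before the gene's lower coordinate, with a fold of 3.75 from 9 fragments, and was assigned to another gene. Of 16 genes named as ZBTB16 targets or partners in mouse work, 4 had a promoter peak in both pig libraries (25%, adjusted exact p = 0.820 against all other genes). These were ETV5 (8.42-fold and 8.29-fold, chromosome 13, 123930074 to 123930653), DDIT4, an inhibitor of mTORC1 (4.56-fold and 5.58-fold, chromosome 14, 75117057 to 75118053), MYC (4.48-fold and 5.54-fold) and GATA2 (4.22-fold and 3.42-fold). KIT, the receptor of differentiating spermatogonia, had a promoter peak in replicate 2 only (3.35-fold, 15 fragments), and its strongest replicate 1 peak was intronic, 67.6 kb from the TSS (4.03-fold). DUSP6 had a promoter peak (4.06-fold) and BCL6B a 5′ UTR peak (3.33-fold) in replicate 1 only. SALL4, BMI1, FOXO1, CCND1, HOXD11, HOXD13, ID2, CEBPA and CRABP1 had no peak assigned in either library. Peaks such as those of KIT, DUSP6 and GATA2 rested on 11 to 18 fragments, a range in which many peaks were found in 1 library only, so absence of a peak means only that none was detected at this depth.

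Promoter peaks were more frequent at cell cycle genes and at genes of mTORC1 signalling, the nutrient- and growth factor-sensing kinase pathway, than at other genes. Of 39 cell cycle genes, 18 had a promoter peak in both libraries (46.2%, 95% Wilson interval 31.6 to 61.4, odds ratio 3.27, adjusted exact p = 0.00590 by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 26 lists). The strongest were CCND3 (8.55-fold and 8.32-fold, chromosome 7, 37182075 to 37182864), CDC25A, a phosphatase that activates cyclin-dependent kinases (8.03-fold and 6.79-fold), MCM3, a subunit of the replicative helicase (8.14-fold and 6.22-fold), and PCNA, the replication clamp (6.43-fold and 5.94-fold). CCND1, CCND2 and CCNE1 had no assigned peak. Of 26 mTORC1 genes, 12 were bound (46.2%, 28.8 to 64.5, odds ratio 3.27, adjusted exact p = 0.0422). Among them were SESN3, a sestrin that inhibits mTORC1 (5.93-fold and 7.15-fold), the RAG GTPases RRAGA (5.77-fold and 5.87-fold) and RRAGC (5.33-fold and 5.54-fold), and DEPTOR, an mTOR-binding inhibitor (6.06-fold and 5.63-fold). TSC1, TSC2 and RHEB had no assigned peak, but each had a peak within 3 kb of the gene that the authors assigned to another gene, since every peak went to 1 gene only. With replicate 2 left out the mTORC1 share was 53.8% against 32.8% of all genes and no longer passed (odds ratio 2.39, adjusted exact p = 0.0887). Among genes with any assigned peak, of which 41.1% were bound, fewer members were left and neither list passed, with lower odds ratios: 18 of 29 cell cycle genes (62.1%, odds ratio 2.35, adjusted exact p = 0.319) and 12 of 19 mTORC1 genes (63.2%, odds ratio 2.46, adjusted exact p = 0.381). Neither passed with peaks above the median fold only (odds ratios 2.29 and 1.82).

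HOX genes, the body-axis homeobox genes, and the markers of hepatocytes and neurons held fewer promoter peaks than other genes. None of 36 HOX genes had one in both libraries (0%, 0 to 9.64, adjusted exact p = 0.00590; 1 of 36 with replicate 2 left out), and HOXA2 and HOXA3 had no assigned peak at all. None of 23 hepatocyte markers, such as ALB, APOA1 and APOA2, and none of 23 neuronal markers, such as SYT1, SYP and STMN2, had one (each 0%, 0 to 14.3, adjusted exact p = 0.0422). APOA2 and SYP had a peak of another gene within 3 kb. HOX genes can lie side by side, as HOXD13 and HOXD11 do on chromosome 15 (starting at 81893997 and 81906654). They are then not independent units, so the HOX p-value and interval may understate the counting error. The other sets of markers from outside the testis had low shares that did not pass: 0 of 19 keratinocyte genes (adjusted exact p = 0.0890; KRT1, KRT2 and KRT4 had no assigned peak) and 1 of 23 skeletal muscle and heart genes (4.35%, adjusted exact p = 0.175), which was TNNI3 (8.17-fold and 5.52-fold), while ACTA1, MYH1 and MYH2 had none. The neuron and hepatocyte calls ended when replicate 1 was reduced to its 7301 strongest peaks (adjusted exact p = 0.0728 for each), the neuron call also with replicate 1 left out (4.35%, adjusted exact p = 0.0975). With peaks above the median fold only, all 3 shares stayed at 0% but did not pass (adjusted exact p = 0.330 for each, against 11.6% of all genes). With replicate 2 left out, the keratinocyte list at 0% (adjusted exact p = 0.00434) and the muscle and heart list at 4.35% (adjusted exact p = 0.0102) also passed as lower, and with replicate 1 left out the keratinocyte list at 0% (adjusted exact p = 0.0339). The keratinocyte list also passed by peaks near gene ends (0%, adjusted exact p = 0.00958) or in genes (5.26%, adjusted exact p = 0.0270).

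**Figure D3:**
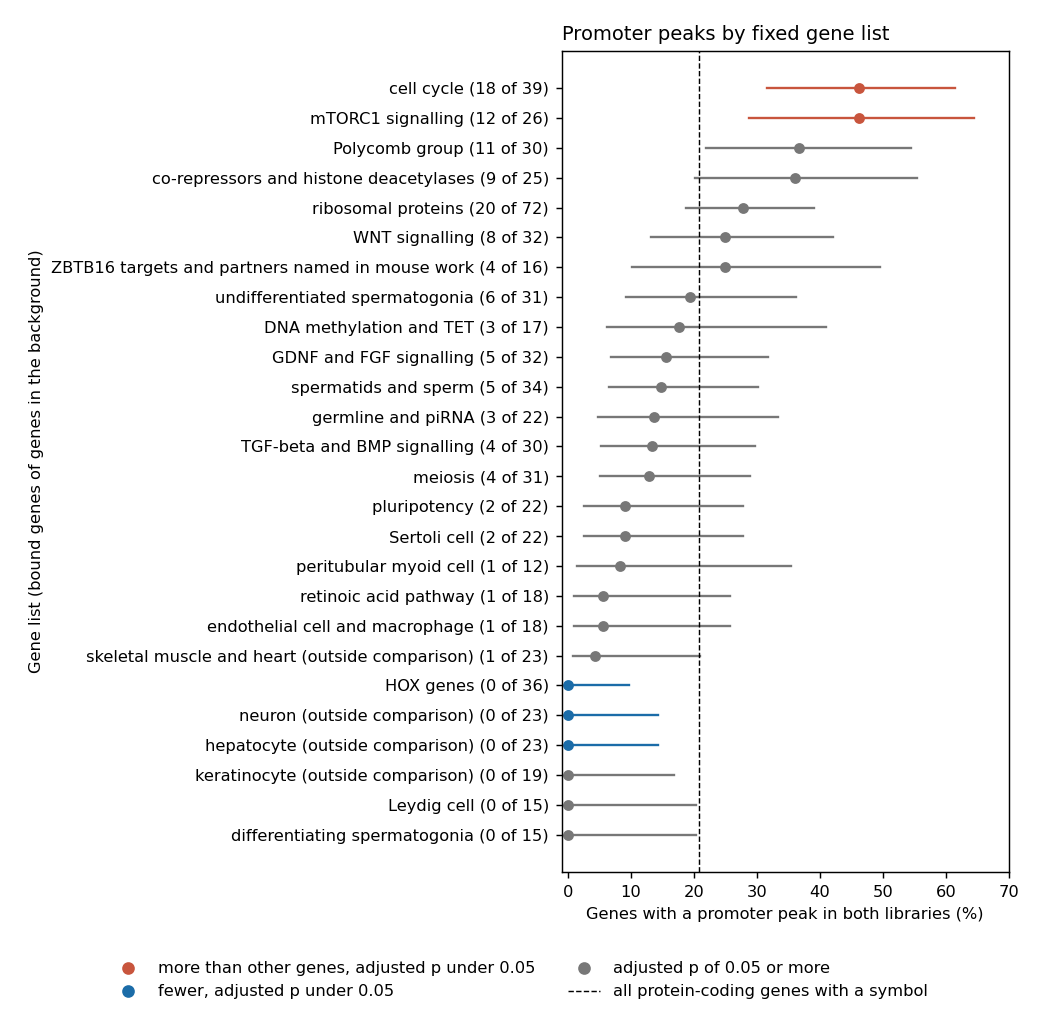
Share of genes (%, x axis) with a promoter peak in both libraries for each of 26 gene lists (y axis, with bound genes of genes in the background); points are shares, lines are 95% Wilson intervals and the dashed line is the share of all 16509 genes, 20.8%. The cell cycle and mTORC1 lists, at 46.2% each, lie above the dashed line past the threshold of 0.05, and the HOX, hepatocyte and neuron lists, at 0%, lie below it.

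By promoter peaks in both libraries, no list of germ cell genes passed the threshold. Of 31 genes of undifferentiated spermatogonia, 6 had a promoter peak in both libraries (19.4%, 9.19 to 36.3, adjusted exact p = 1), led by ETV5, TAF4B, a germ cell TFIID subunit (4.69-fold and 4.52-fold), EGR2 (4.16-fold and 4.97-fold) and PIWIL4, a piRNA-binding protein (4.15-fold and 4.47-fold). SALL4 and NANOS2, like ZBTB16, had no assigned peak. Differentiating spermatogonia had 0 of 15 (adjusted exact p = 0.151), with no assigned peak at DMRT1, DMRTB1 and SOHLH1, and had 13.3% with replicate 1 left out (adjusted exact p = 0.625), 20% with replicate 2 left out (adjusted exact p = 0.564) and 20% with any assigned peak. It passed as lower only by peaks within 1 kb of either gene end (0 of 14, adjusted exact p = 0.0426). By promoter peaks in both libraries, a list of 15 genes could not pass as lower even with none bound. The germline and piRNA list had 3 of 22 (13.6%, adjusted exact p = 0.708): MAEL (5.68-fold and 4.48-fold), TDRD7 (4.24-fold and 4.85-fold) and HENMT1 (5.53-fold and 3.85-fold). DDX4, PIWIL1 and TDRD1 had none. Meiotic genes had 4 of 31 (12.9%, adjusted exact p = 0.544): MEIOB (7.18-fold and 6.66-fold), HSPA2 (7.29-fold and 5.39-fold), SYCE3 (4.96-fold and 5.12-fold) and MSH5 (6.65-fold and 4.85-fold), with none at SYCP1, SYCP3 and TEX12. Genes of spermatids and sperm had 5 of 34 (14.7%, adjusted exact p = 0.651), among them TEKT1 (6.90-fold and 6.39-fold), CATSPER2 (6.76-fold and 5.30-fold), ODF2 (5.08-fold and 8.45-fold) and HOOK1 (5.93-fold and 5.05-fold), with none at PRM1, PRM2 and TNP1. A single library is a looser criterion, which bound 24.9% of all genes with replicate 1 left out and 32.8% with replicate 2 left out. The germline and piRNA share then became 22.7% and 36.4%, the meiotic share 19.4% and 32.3%, and the share of spermatids and sperm 17.6% and 20.6%, none passing.

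Markers of the other cell types of the testis had few promoter peaks, and none of these lists passed by promoter peaks in both libraries. Sertoli cell genes had 2 of 22 (9.09%, adjusted exact p = 0.471), KITLG (4.54-fold and 5.66-fold) and TF (5.0-fold and 4.0-fold), with no assigned peak at SOX9, SOX8 and AMH. Leydig cell genes had 0 of 15 (adjusted exact p = 0.151), with none at STAR, CYP17A1 and HSD3B1, and passed as lower at 0% with replicate 2 left out (adjusted exact p = 0.0134), by peaks within 1 kb of either gene end (adjusted exact p = 0.0276) and by peaks in the gene or within 1 kb of it (adjusted exact p = 0.0142). Counting any assigned peak, 3 of these 15 genes had one in both libraries. By promoter peaks in both libraries, a list of this size could not pass as lower. Peritubular myoid cell genes had 1 of 12 (8.33%, adjusted exact p = 0.651), TAGLN (4.44-fold and 4.68-fold), and endothelial cell and macrophage genes 1 of 18 (5.56%, adjusted exact p = 0.274), KDR (5.95-fold and 5.12-fold). That list passed as lower by peaks in the gene or within 1 kb of it (5.56% against 34.3% of all genes, adjusted exact p = 0.0389). ACTA2, DES, CDH5 and TEK had no assigned peak, and MYH11 and PECAM1 only a peak of another gene within 3 kb. With replicate 1 and with replicate 2 left out, the shares were 9.09% and 13.6% for Sertoli, 16.7% in both cases for peritubular myoid, and 1 and 2 of 18 for endothelial and macrophage genes.

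Signalling lists other than mTORC1 did not pass. WNT signalling had 8 of 32 (25%, adjusted exact p = 0.651), with GSK3B at 10.2-fold and 8.56-fold (chromosome 13, 140135309 to 140136076), AXIN1 at 5.95-fold and 6.16-fold, CTNNB1 at 5.45-fold and 7.39-fold and ZNRF3 at 6.36-fold and 4.80-fold. GDNF and FGF signalling had 5 of 32 (15.6%, adjusted exact p = 0.749), among them YES1 (7.14-fold and 5.57-fold) and MAP2K1 (5.49-fold and 6.86-fold). TGF-beta and BMP signalling had 4 of 30 (13.3%, adjusted exact p = 0.544): SMAD2 (6.18-fold and 6.58-fold), SMAD4 (5.31-fold and 4.02-fold), ACVR1B (3.75-fold and 4.12-fold) and ID4, an inhibitor of helix-loop-helix factors that marks spermatogonial stem cells in mouse (3.68-fold and 3.89-fold). The retinoic acid pathway had 1 of 18 (5.56%, adjusted exact p = 0.274), ALDH1A2 (4.39-fold and 3.79-fold). With replicate 1 and with replicate 2 left out, the shares were 28.1% and 40.6% for WNT, 21.9% and 34.4% for GDNF and FGF, 26.7% and 23.3% for TGF-beta and BMP, and 2 and 3 of 18 for retinoic acid, none passing. Against the 24.9% and 32.8% of all genes, GDNF and FGF rose above with replicate 2 left out and TGF-beta and BMP with replicate 1 left out.

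Among chromatin regulators, 11 of 30 Polycomb group genes (36.7%, 21.9 to 54.5, adjusted exact p = 0.151) and 9 of 25 co-repressor and histone deacetylase genes (36.0%, 20.2 to 55.5, adjusted exact p = 0.190) were bound, which did not pass. With replicate 2 left out, 19 of 30 Polycomb genes were bound (63.3%, adjusted exact p = 0.00434). The strongest were RBBP4 (7.05-fold and 6.61-fold), PHF1 (6.23-fold and 6.76-fold), PCGF1 (7.33-fold and 5.88-fold) and PHC2 (7.20-fold and 5.32-fold) of the Polycomb list, and HDAC4 (11.3-fold and 8.19-fold, chromosome 15, 138657509 to 138658267), HDAC2 (6.49-fold and 6.72-fold), HDAC1 (6.27-fold and 6.63-fold) and SAP30 (5.33-fold and 6.21-fold) of the co-repressor list. BMI1 and RBBP7 had no assigned peak, and SUZ12 only a peak of another gene within 3 kb. The list of DNA methylation and TET genes had 3 of 17 (17.6%, adjusted exact p = 1), TDG, DNMT1 (7.05-fold and 7.72-fold) and GADD45A (5.39-fold and 4.94-fold). Pluripotency genes had 2 of 22 (9.09%, adjusted exact p = 0.471), MYC and TBX3 (4.39-fold and 5.02-fold), with none at POU5F1, NANOG and SOX2. With replicate 2 left out, the shares were 52.0% for co-repressors, 29.4% for DNA methylation and 27.3% for pluripotency genes, against 32.8% of all genes, none passing. Ribosomal protein genes had 20 of 72 (27.8%, 18.8 to 39.0, adjusted exact p = 0.274), led by RPS25 (7.09-fold and 7.22-fold) and RPLP2 (7.05-fold and 6.42-fold). With replicate 2 left out, 36 of 72 were bound and the list passed as higher (50%, adjusted exact p = 0.0102).

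Peaks strong in replicate 1 tended to be strong in replicate 2. Across the 5468 shared peaks the Spearman correlation of fold enrichment was 0.58 and the Pearson correlation of log2 fold enrichment was 0.64. It was 0.59 (Spearman) over the 4179 promoter peaks and 0.50 over the 311 distal ones. These are correlations across peaks, which are not independent replicates, so no p-value is given.

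The 5 strongest shared distal peaks lay outside gene bodies. The first was on chromosome 15 (126761698 to 126762721), 49.9 kb upstream of DOCK10, with a fold of 29.6 in replicate 1 and 27.6 in replicate 2. The second was on chromosome 4 (53953105 to 53954088), 627 kb from the gene it was assigned to, with 24.6-fold and 22.6-fold. Another lay on an unplaced scaffold 4.74 kb from RN5-8S, a 5.8S ribosomal RNA gene, with 18.1-fold and 17.6-fold, and a further one on an unplaced scaffold had 18.7-fold and 17.6-fold. The last was on the Y chromosome (43257485 to 43258030), with 18.8-fold and 16.9-fold. The background recovered in replicate 1 was 31.1 fragments for the DOCK10 peak, 100.5 for the chromosome 4 peak and 18.9 for the RN5-8S peak. For the other scaffold peak it was 7.14. All of these lay above the 95th percentile of 5.66 over all shared peaks, and the Y chromosome peak, at 1.93, lay below it.

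The X chromosome carried fewer shared peaks than autosomes for its length. It held 86 of the 5379 shared peaks on X and autosomes (1.599%, exact 95% interval 1.28 to 1.97), where its share of length would give 5.27% (two-sided exact binomial p = 1.77e-44), or 0.683 peaks per Mb against 2.34 on autosomes. For promoter peaks the share was 1.595% against 3.74% of protein-coding genes with a symbol (exact binomial p = 5.88e-16). One X-linked gene bound in both libraries was TBC1D25. Male cells carry 1 X chromosome, which can lower the signal there. The expected shares above make no allowance for the single copy, and how much of the difference it accounts for was not tested. The Y chromosome held 13 peaks in replicate 1 and 9 in replicate 2.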

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

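The backgrounds with LOC-numbered genes, the peaks near or within genes irrespective of the authors' assignment, the exclusion of scaffolds, the promoter-only overlap, the use of replicate 2 classes and the summit-fragment correlation were chosen after seeing the data; the rest was planned. No result that passed its test changed direction, while several gene lists that did not pass crossed the share of other genes under an alternative without passing. Overlap between the libraries stayed past the threshold under all 7 alternatives (25.2% to 63.7% of replicate 1 peaks), as did the lower X share (1.57% to 2.10%). The promoter share was 60.8% to 64.0% with each library alone. Genes with a promoter peak numbered 1914 with peaks above the median fold, and 4115 to 5415 with each library alone, since 1 list is a looser criterion. With peaks above the median fold, 0 lists lay higher and 0 lower: cell cycle 23.1%, mTORC1 19.2%, HOX, hepatocyte and neuron 0%, with adjusted exact p from 0.330 to 0.444; fewer genes were bound by construction. Among genes with any peak it was also 0 and 0, with cell cycle 62.1% and mTORC1 63.2% against 41.1% of all genes (odds ratios 2.35 and 2.46, on 29 and 19 genes) and the other 3 at 0%; it leaves only 3 HOX, 2 hepatocyte and 8 neuron genes, too few for the first pair to pass, so it does not bear on them. With equal list lengths, and with LOC-numbered genes, 1 list lay lower, and hepatocyte and neuron were at 0% (adjusted exact p = 0.0728 and 0.0924). Counting any assigned peak gave neuron 13.0% (adjusted exact p = 0.381). Lists lying lower numbered 6 with a peak within 1 kb of either gene end, and 6 with one in the gene or 1 kb of it; the cause was not tested. With each library alone, lists lying lower numbered 3 to 6, neuron was 4.35% to 8.70% and mTORC1 50.0% to 53.8%. The correlation was 0.65 for −log10 q, 0.46 for width and 0.77 for summit fragments. Of lists that had not passed, 14 results passed under an alternative, among them ribosomal proteins at 47.2% and 51.4% under the gene-end and in-gene settings. Motif searches and the GC-matched background were not run. In the lowest quartile by fragments, 15.7% of replicate 1 peaks (7 to 12) and 38.1% of replicate 2 peaks (6 to 11) were shared, so depth limits statements on weak sites. No paired analysis was possible because there is 1 group.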

Other observations

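The tests by shared symbol prefix, of pooled lists, of background and of the spermatogonial list under the alternatives were chosen after seeing the data, and the genes named here were chosen after their values were seen. Grouping genes by symbol prefix gave 117 families of at least 15 genes, of which 6 had more and 8 had fewer genes with a promoter peak in both libraries than other genes (adjusted p under 0.05, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the families). The CEP family of centrosomal proteins stood highest, with 23 of 36 genes (63.9%, 95% Wilson interval 47.6 to 77.5, adjusted exact p = 3.09e-06), among them CEP131 (9.14-fold in replicate 1 and 7.38-fold in replicate 2), CEP89 (8.24-fold and 9.31-fold) and CEP19 (8.02-fold and 6.99-fold). Of the adaptor-related AP prefix, 14 of 29 genes were bound (48.3%, adjusted exact p = 0.0174). The DHX helicases had 9 of 16 (56.3%, adjusted exact p = 0.0327), the general transcription factors of the GTF prefix 11 of 22 (50.0%, adjusted exact p = 0.0327), translation factors of the EIF prefix 19 of 49 (38.8%, adjusted exact p = 0.0434) and TBC domain genes 13 of 30 (43.3%, adjusted exact p = 0.0449). EIF3M had 10.2-fold and 7.56-fold and GTF3C5 10.3-fold and 8.72-fold. A prefix can hold unrelated genes, as COL4A3BP in the COL group shows. Genes of 1 family can also lie side by side and are then not independent units, so the family p-values may understate the counting error.

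Lower shares were found for interleukins and their receptors (IL prefix, 2 of 78, 2.56%, adjusted exact p = 0.000247), orphan G protein-coupled receptors (GPR, 3 of 72, 4.17%, adjusted exact p = 0.00430), solute carriers (SLC, 46 of 354, 13.0%, adjusted exact p = 0.00445), keratins (KRT, 0 of 35, adjusted exact p = 0.0120), cytochromes P450 (CYP, 1 of 37) and KLHL genes (1 of 37, each 2.70% with adjusted exact p = 0.0421), collagens (COL, 2 of 44, 4.55%, adjusted exact p = 0.0449) and phosphodiesterases (PDE, 0 of 25, adjusted exact p = 0.0449). The single bound members were CYP51 and KLHL13. Calls for CEP, DHX, EIF, IL, GPR, SLC, KRT, CYP and COL passed again with replicate 1 left out and with replicate 2 left out. The other calls did not hold: KLHL (8.11% with replicate 1 left out and 18.9% with replicate 2 left out, against 24.9% and 32.8% of all genes, adjusted exact p = 0.0916 and 0.195), PDE (4.0% and 12.0%, adjusted exact p = 0.0642 and 0.0980), GTF (50% and 59.1%, adjusted exact p = 0.0642 and 0.0602) and TBC (46.7% and 53.3%, adjusted exact p = 0.0642 and 0.0791) ended in both cases, and AP with replicate 1 left out (48.3%, adjusted exact p = 0.0588). Shares of the families that held also rose with replicate 2 left out, such as IL to 8.97%, GPR to 9.72%, CYP to 8.11% and COL to 11.4%. By peaks within 1 kb of either gene end, SLC (23.7% against 29.3% of all genes, adjusted exact p = 0.0697) and CYP (10.8%, adjusted exact p = 0.0511) did not pass. The 4 sets of markers from outside the testis together had 1 of 88 genes bound (1.14%, adjusted exact p = 1.28e-07 over 3 pooled sets), the 4 somatic testis lists 4 of 67 (5.97%, adjusted exact p = 0.00197), and the 5 germ cell lists 18 of 133 (13.5%, adjusted exact p = 0.0410). The outside share was 3.41% with either library left out and 6.82% with any assigned peak, and the somatic share 7.46% with replicate 1 left out, 10.4% with replicate 2 left out and 13.4% with any assigned peak. Both stayed lower under every alternative (unadjusted exact p at most 0.00128 and 0.0302). The germ cell value did not pass with replicate 1 left out (19.5%, unadjusted exact p = 0.160) or replicate 2 left out (27.1%, unadjusted exact p = 0.165). It also did not pass within 1 kb of the TSS (unadjusted exact p = 0.104), with LOC-numbered genes (0.300), with any assigned peak (0.439) or among genes with any peak (0.0683), and germ cell and somatic lists were not told apart by a direct test (Fisher's exact p = 0.150). TEX14, a gene of germ cell intercellular bridges, had 5 assigned peaks in replicate 1 and 3 in replicate 2, but no promoter peak in both. Genes outside the germ cell lists had as many or more, such as COLGALT1 (5 and 3) and LOC110260819 (8 and 8).

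Of the 20 strongest shared peaks, 9 lay outside promoters (45.0%, against 23.6% of all shared peaks), among them those near DOCK10 and near the ribosomal RNA gene RN5-8S. Regions with high background, such as collapsed repeats or ribosomal DNA, are a candidate explanation. The median background recovered for these 9 peaks was 18.9 fragments in replicate 1 and 14.2 in replicate 2, but the 11 promoter peaks of the same 20 had medians of 6.43 and 5.10, and both sets lay above the 95th percentiles of 5.66 and 4.30 over all shared peaks. An exact rank test between these sets gave p = 0.230 and 0.152. In replicate 1 the Y chromosome peak (1.93 fragments) lay below the median background of 2.85 over all shared peaks. The chromosome 4 peak near 46447451 (2.89) lay close to that median. With so few peaks the explanation stays open, and no biological explanation was tested.

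Replicate 2 had fewer peaks than replicate 1, in a ratio of 1.41. Lower depth of replicate 2 is consistent with its lower genome background (0.979 against 1.21 fragments) and with the 90.9% of replicate 1 peaks in the highest quartile by summit fragments that overlapped a replicate 2 peak. Another class of sites in replicate 1 was also considered. Within the lowest quartile, the promoter share of shared peaks exceeded that of replicate 1-only peaks by 23.2 percentage points (49.6% against 26.5%), with narrower gaps in the other quartiles (67.4% against 50.6%, 77.2% against 63.4% and 84.5% against 73.0%). Replicate 2-only peaks were also poor in promoters (34.0% against 74.0% of shared peaks). This held within the lowest quartile of replicate 2 too (22.6% against 52.2%). A gap that arose in both libraries cannot show a class of sites particular to replicate 1, so the test does not decide this explanation. No biological explanation was tested, since both libraries belong to 1 group.

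Promoter peaks differed between gene lists, and promoters open in most cells might carry peaks whatever the antibody. Ribosomal protein genes had a share of 27.8%, above the 20.8% of all genes but not past the threshold, and 2 of the 4 outside lists passed on the lower side. With replicate 2 left out everything this explanation needs was there (ribosomal proteins 50%, adjusted exact p = 0.0102, cell cycle 66.7%, and all 4 outside lists lower). The ribosomal list also passed as higher by peaks near gene ends (47.2% against 29.3% of all genes) or in genes (51.4% against 34.3%). With peaks above the median fold, where no list passed, its share was 9.72% against 11.6% of all genes. Signal at open promoters cannot be told apart from binding without a control library. A preference for spermatogonial genes was tested by setting the 31 undifferentiated spermatogonia genes (19.4%) against the cell cycle genes (46.2%, unadjusted exact p = 0.0238) and the ribosomal proteins (27.8%, unadjusted exact p = 0.462). Its share lay below the cell cycle list with p under 0.05 in 11 of 12 settings, all but genes with any peak (46.2% against 62.1%, unadjusted exact p = 0.501). These settings reuse the same genes, and with LOC-numbered genes the test is identical to the main one, so the count is not independent support. In these peak lists the main comparison argues against a preference over cell cycle genes, but unspecific signal at open promoters was not separated from binding. Over ribosomal proteins a preference was not seen, but the main comparison did not exclude it. The spermatogonial share lay below the ribosomal one in 11 of 12 settings, with p under 0.05 in 3 of them. The lowest was by gene ends (19.4% against 47.2%, unadjusted exact p = 0.00854). Among genes with any peak the spermatogonial share was the higher one (46.2% against 42.6%, unadjusted exact p = 1).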
